A study of Homo sapiens with 3 samples.

How the data were processed

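RNA of MCF-7 cells from 3 samples, control, rapamycin and PP242, was measured on Agilent one-colour (Cy3) human miRNA arrays, 1 array per sample. Per the labels' protocols, total RNA was isolated with TRIZOL and 100 ng was labelled. Per the file headers, the scanned arrays were read by Agilent Feature Extraction 10.7.3.1, whereas the submitters' processing notes name version 9.5.3. The deposited scanner files give each spot's intensity on a linear scale, background-subtracted by that software per the file headers, with values below 0 for dim spots, together with a total signal and a detection call per miRNA. The deposited table of the whole series gives log2 values that the authors normalized in a way not given in the sources used here. Compared with the scanner files, its 961 values per array, control entries included, followed log2 of the total signal per miRNA in rank (Spearman 1.00 on detected miRNAs), and its columns shared 1 distribution with a median of 1.35 each, as quantile normalization gives. Scale and direction were settled by that match, and no centring of miRNAs was seen. No value in it was at or below 0 (lowest 0.85).

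Each array carried 15024 spots of miRNA probes for 939 entries, 851 human and 88 viral, with 16 spots and 1 to 4 probes per miRNA. miRNA names are those of the array design, and the strand names ending in an asterisk are kept as printed there. Spots the software marked as non-uniform or as population outliers were left out, 8.93% on the control array, 9.74% with rapamycin and 7.39% with PP242, and 0 spots were saturated. The processed signal was averaged over the spots of a probe, summed over the probes of a miRNA, divided by the array's 75th percentile over the 133 miRNAs detected on all 3 arrays (491, 601 and 513 for control, rapamycin and PP242) and taken to log2. A miRNA counted as detected where the software called it so, which the files bore out as any probe whose total signal exceeded 3 times its error. The error floors differed: the additive error was 4.45 on the control array, 2.95 with rapamycin and 2.86 with PP242, and the number of arrays, 1 per group, limits the precision throughout.

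Ratios were counted over miRNAs detected on both arrays of a comparison. A miRNA detected on 1 of them got a bound, the bright scaled signal over the higher of the dim array's lowest detected scaled signal and its own dim value. Where its dim value was the higher, the bound is the ratio of both measured signals, with no allowance for error, and it can fall below 1. Rapamycin against control had 135 miRNAs detected on both arrays and 134 ratios, since miR-298 had a signal below 0 on the control array. Spot standard errors were carried from the spots of each probe to the log2 ratio. As 1 array per group allows no test, a difference of at least 2-fold was counted as a call of size. The miRNAs to name were set by a rule: up to 10 highest and 10 lowest human miRNAs past 2-fold against the control and the 3 largest bounds of at least 2 each way, 5 and 2 of these between the drugs, and up to 3 members with the highest mean signal of each list. Any other miRNA is named as chosen after the values were seen, or because it belongs to a count of 5 or fewer or to a list that stood apart. For 30 fixed lists of miRNA families, clusters, cell type markers and array entries of special kinds, the median log2 ratio was placed among 10000 random lists of the same size, drawn from the 133 miRNAs within deciles of mean signal, and 21 lists had at least 2 detected members. Correlations across miRNAs were set against 2000 simulations of unchanged arrays that share a control. The rules, lists and most alternatives were fixed before the data were examined.

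The alternatives were the software's total signal per miRNA, normexp background correction with an offset of 50 (limma 3.58.1 in R 4.3.3), other scalings (75th percentile over all entries, median, quantile, none), the brightest probe or the mean of log2 values over probes, the median over spots, odd or even spots, outlier spots kept, no detection filter, a stricter filter, another detection call, a 1.5-fold rule and the deposited series values. Added after the data were seen were scaling to the labelling spike-ins, leaving out miR-150*, the GC-rich list without miR-1290, miR-1305 and miR-574-5p, the list of structural RNA pieces with miR-923, normexp refitted without spots not above their background, 50 added to each probe without normexp, and human miRNAs only. As the files hold no mean signal column, normexp used the median signal of each spot with the median background. Other work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

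The steps were tested on simulated data. For PP242 against control, arrays of the 133 miRNAs were drawn from the real probe means and spot spreads with known folds, and the 2-fold rule called 1.0% of 500 miRNAs with a true fold of 1.5, 98.6% of 500 with 2.5, 100% of 500 with 4, and 0.1% of 5150 without a change. These shares include spot error only and no variation between arrays. For the lists, the same 133 names were given normally distributed ratios and random brightness in place of the measured ones. Of 200 random lists of 5, 5.0% fell outside the central 95%, about the share the method sets in advance. Of 200 lists shifted by 0.5 on the log2 scale 80.5% were found, a share that holds for such ratios only. Genome coordinates of the miRNAs were not used here.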

Results

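The miRNAs of MCF-7 cells, an established human breast cancer line of the luminal, oestrogen receptor-positive type, were measured after inhibition of mTOR, the kinase at the core of the growth-controlling complexes mTORC1 and mTORC2. Per its title, the series screened for miRNAs regulated through either complex. The data were 3 one-colour miRNA arrays with 1 array each for control cells, cells given 100 nM rapamycin and cells given 200 nM PP242. Rapamycin binds FKBP12 and inhibits mTORC1 allosterically, whereas PP242 competes with ATP and inhibits the mTOR kinase in both complexes. Drug was present for 24 h without serum and for a further 24 h after serum was returned, 48 h in all. The labels do not say whether the control cells were also starved and refed or got a vehicle, so the ratios to control can include such a difference. With 1 array per group there was no replicate check, so no p-value was computed, and differences were described by a fixed 2-fold rule of size. The standard errors given are over the spots of a miRNA within an array and cover technical error within that array only. All 3 arrays lay on 1 slide, where the array position and the treatment cannot be told apart.

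The let-7 and miR-200 families and most of the listed luminal miRNAs were detected on every array. The let-7 family, which represses RAS and other growth genes, had 9 of 9 members detected on all 3 arrays, and the miR-200 family, which holds down the ZEB repressors of E-cadherin, had 5 of 5. Of 8 miRNAs on a list fixed under the name of luminal breast epithelial miRNAs, 6 were detected on all 3 arrays. These were miR-21, miR-203, miR-342-3p, miR-375, miR-489 and miR-7. The others, miR-205 and miR-190b, were detected on no array. Whether each listed miRNA marks luminal cells was not tested, so their absence is not read against a luminal identity. miR-21 took 58.6% of the summed signal on the control array, 58.4% with rapamycin and 59.1% with PP242. Few markers of other cell types were detected. None of the 8 blood cell miRNAs, such as miR-223 and miR-451, was detected on any array. miR-126, enriched in endothelium, was the 1 detected miRNA of 9 stromal, muscle and endothelial miRNAs, with log2 ratios to control of -0.004 (spot SE 0.08) with rapamycin and 0.01 (spot SE 0.08) with PP242. Of 5 neural and liver miRNAs, miR-128 was detected on the control array, and miR-128 and miR-9 on each treated array. miR-221 and miR-222, and all 45 entries of the primate-specific C19MC cluster on the array, were detected on no array. In all, 145 of 939 miRNA entries were detected on the control array, 197 with rapamycin and 163 with PP242, and 133 were detected on all 3. Viral entries, for miRNAs that uninfected cells should lack, gave 2, 6 and 2 of these detections. Spike-in RNAs of the labelling step were brighter on the treated arrays, by 1.37 and 1.48-fold with rapamycin and by 1.33 and 1.36-fold with PP242.

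Rapamycin against control asked which miRNAs depended on the rapamycin-sensitive part of mTOR signalling. With rapamycin, miR-150*, the passenger strand of the hairpin that yields the lymphocyte miRNA miR-150, was 3.83-fold higher than in the control (log2 ratio 1.94, spot SE 0.36). The guide strand miR-150 itself was detected on no array. miR-150* was the only miRNA at least 2-fold higher among 134 with a ratio, and 0 were at least 2-fold lower. The other values were closely grouped: 125 miRNAs (93.3%) lay within 1.5-fold of the control, and the SD of the log2 ratios was 0.30. Beyond 1.5-fold, as a choice made after the values were seen, were miR-197 above the control (0.65, spot SE 0.11) and 7 entries below it. These 7 included miR-494, the 1 miRNA detected among 32 listed ones of the imprinted 14q32 cluster (-0.64, spot SE 0.05), miR-424 of the miR-15/16 seed family (-0.75, spot SE 0.15), and miR-923, since recognised as a piece of 28S ribosomal RNA (-0.68, spot SE 0.03).

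The value of miR-150* with rapamycin rested partly on an uneven probe. Its brightest probe, the only probe of 4 that was well above background on all 3 arrays, read 27.9 ± 5.33 (SD over 4 spots) on the control array and 64.3 ± 4.22 (SD over 4 spots) on the rapamycin array, 1.88-fold apart after scaling. A second probe ranged from 8.55 to 130.5 over 4 spots on the rapamycin array. With the brightest probe of each miRNA only, the log2 ratio of miR-150* was 0.84, under 2-fold, and with normexp background correction it was -1.01. The normexp fit of the control array was off, with corrected spots at a median of 255.2 against 61.1 and 60.5 on the treated arrays. Refitted without 8 control spots that were not above their local background, a step added after the values were seen, normexp gave 0.15 for miR-150*. The count of 1 higher and 0 lower became 1 and 7 with scaling to the 75th percentile over all entries, 2 and 2 with quantile normalization and 1 and 1 with scaling to the labelling spike-ins. It became 0 and 34 with normexp, 0 and 0 with the refitted normexp and 11 and 8 with no detection filter.

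**Figure D1:**
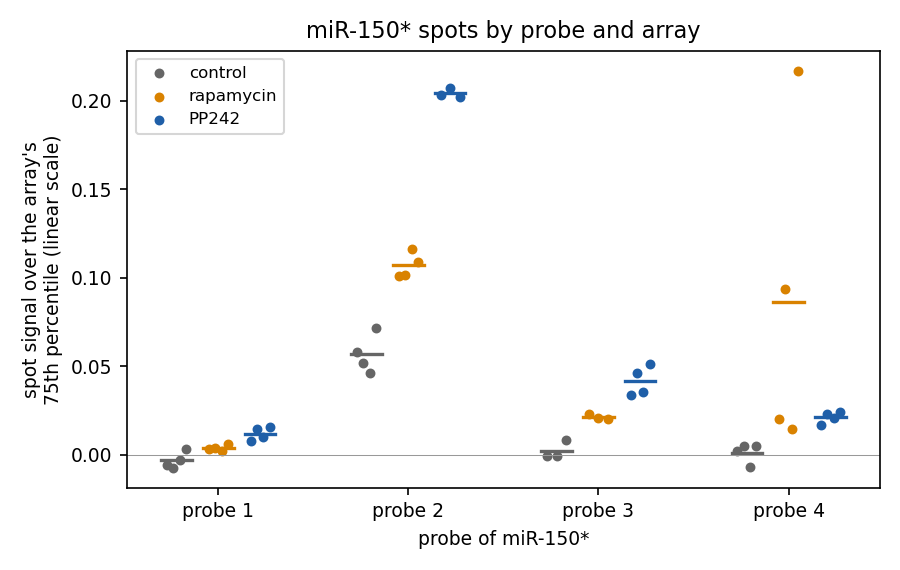
Signals of the spots of miR-150* on the control (grey), rapamycin (orange) and PP242 (blue) arrays, by probe, divided by the array's 75th percentile over 133 detected miRNAs (y axis, linear scale, no unit). Points are spots without outlier marks and short lines their means; probe 2 separated the 3 arrays, whereas probe 4 was uneven with rapamycin, with unscaled spots from 8.55 to 130.5.

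The fixed miRNA groups mostly stayed close to the control with rapamycin. The median log2 ratio over all 133 miRNAs was -0.01, and list medians are read against it. Members are counted where detected on all 3 arrays. All 9 detected let-7 members lay slightly below the control, with a median of -0.07 at percentile 29.0 of 10000 random lists matched on signal. Relative to the median miRNA this was -0.06, and it became 0 with quantile normalization and in the deposited series values. let-7a stood at -0.13 (spot SE 0.05) and let-7f at -0.02 (spot SE 0.04). The miR-17~92 cluster, a growth-promoting target of MYC, had 3 of 5 members lower and a median of -0.12 (percentile 13.1), with miR-19b at -0.15 (spot SE 0.03) and miR-20a at -0.15 (spot SE 0.05). The miR-200 family had 5 of 5 members lower and a median of -0.08 (percentile 20.9), and the luminal list had 5 of 6 lower and a median of -0.08 (percentile 25.2). The luminal median relative to all miRNAs became 0 with quantile normalization. The miR-29 family, known for its collagen targets, had 3 of 3 members higher with a median of 0.24 (percentile 84.2), and miR-29a, miR-29b and miR-29c lay at 0.24, 0.25 and 0.23. The miR-30 family had 4 of 4 higher with a median of 0.15 (percentile 88.0). miR-210, induced by hypoxia, had a log2 ratio of -0.19 (spot SE 0.07).

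Of the 21 lists with at least 2 detected members, 2 lay outside the central 95% of random lists with rapamycin. A fixed list of array entries that are pieces of tRNA, ribosomal, small nuclear or other structural RNAs, which did not include miR-923, had a median of -0.23 (percentile 0.14), with 6 of 8 members lower. Its members included miR-1308 at -0.61, miR-720 at -0.21 (spot SE 0.06), miR-1260 at -0.09 (spot SE 0.15) and miR-1274b at 0.03 (spot SE 0.07). The highest member was miR-1246 at 0.19 (spot SE 0.15). With normexp background correction that median was 0.05, at percentile 76.3, and with the refitted normexp -0.17 (percentile 1.16), and without scaling it was 0.06, where the median over all miRNAs was 0.28 and the percentile stayed at 0.14. With miR-923 added, a choice made after its value was seen, the median was -0.25 with 7 of 9 lower (percentile 0). The 2 detected viral entries, ebv-miR-BART13 and kshv-miR-K12-3, had log2 ratios of -0.76 (spot SE 0.08) and -0.80 (spot SE 0.36) and a median of -0.78 (percentile 0.27). The viral list left the outer range with normexp, with even-numbered spots only and with outlier spots kept.

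More miRNAs were called detected with rapamycin than in the control. There were 62 miRNAs detected with rapamycin and not in the control, and 10 the other way. For these a bound was computed, the brighter signal over the higher of the dim array's detection floor and the dim signal. Where the dim signal was the higher, the bound is the ratio of both measured signals, with no allowance for error. The bound reached 2-fold for 9 of the 62 and 6 of the 10, and some of the 62 had the higher scaled signal in the control. miR-374b* had a bound of at least 6.09-fold higher with rapamycin (signal 73.0, spot SE 27.1) and miR-335* of 3.22-fold (38.5, spot SE 7.74). miR-586 had a ratio of measured signals of 2.36-fold (39.2, spot SE 16.1). When each probe's mean was replaced by the median of its spots, the first 2 were still called detected and miR-586 was not. The largest bounds on the lower side, 5.67-fold for miR-609, 3.47-fold for miR-338-5p and 2.72-fold for miR-876-5p, came from control signals of 46.9, 28.7 and 22.5 with spot SEs of 37.9, 26.6 and 11.4. None of these 3 was still called detected with the spot medians, as for 6 of the 10 miRNAs detected on the control array alone, so their bounds do not show a lower level.

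PP242 against control asked the same of the inhibition of both complexes. With PP242, miR-150* was 4.89-fold higher than in the control (log2 ratio 2.29, spot SE 0.18), the only miRNA at least 2-fold higher among 133, although with normexp the log2 ratio was -0.72 and with the refitted normexp 0.44. Its brightest probe read 104.8 ± 1.44 (SD over 3 spots) with PP242, 3.59-fold above the control after scaling. The 1 entry at least 2-fold lower was viral, ebv-miR-BART13 of the Epstein-Barr virus, at -1.04 (spot SE 0.09), so no human miRNA was 2-fold lower. Within 1.5-fold lay 120 miRNAs (90.2%), and the SD of the log2 ratios was 0.37. Beyond 1.5-fold, again chosen after the values were seen, 8 entries were higher and 5 lower. Among the 8 was miR-21*, the passenger strand of the miR-21 hairpin, at 0.66 (spot SE 0.04), whereas the guide strand miR-21, an oncogenic miRNA of breast cancer, was at 0.02 (spot SE 0.06). miR-181a stood at 0.65 (spot SE 0.08) and miR-197 at 0.67 (spot SE 0.10). Among the 5 were miR-424 (-0.65, spot SE 0.16), miR-923 (-0.58, spot SE 0.04) and the dim miR-183* (-0.87, spot SE 0.56).

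With PP242 the members of a few miRNA families lay above the control, but none reached 2-fold. In the main processing each family's median lay within the central 95% of random lists. The median log2 ratio over all 133 miRNAs was 0.04. With scaling to the labelling spike-ins it was -0.33, and the single values shift with it, so families are read relative to the median. Relative to it the miR-30, miR-29, miR-181 and miR-15/16 medians were 0.35, 0.31, 0.42 and 0.15, whereas with the spike-ins their medians over the control were 0.02, -0.02, 0.09 and -0.18. The miR-30 family had 4 of 4 members higher and a median of 0.39 (percentile 96), with miR-30c at 0.48 (spot SE 0.13), miR-30d at 0.47 (spot SE 0.04) and miR-30b at 0.20 (spot SE 0.08). The miR-29 family had 3 of 3 higher and a median of 0.34 (percentile 92.5), with miR-29a at 0.56 (spot SE 0.06). The miR-181 family had its 2 detected members higher and a median of 0.45 (percentile 94.9). The miR-15/16 seed family, which represses BCL2 and cyclins, had 5 of 6 higher and a median of 0.19 (percentile 90.9). Its median came outside the range with the refitted normexp (percentile 98.3) and with 50 added to each probe (97.7). Its miR-16 stood at 0.33 (spot SE 0.03) and its miR-15a at 0.10 (spot SE 0.04), and miR-424 was the member that lay below the control. The let-7 family had 6 of 9 members higher and a median of 0.01 (percentile 35.6), which was -0.03 relative to the median miRNA and became 0 with quantile normalization and in the deposited series values. On the lower side, miR-210 was at -0.45 (spot SE 0.05). The miR-17~92 cluster had 4 of 5 members lower and a median of -0.12 (percentile 19), with miR-19b at -0.24 (spot SE 0.03) and miR-17 at -0.01 (spot SE 0.12). The miR-200 family had 3 of 5 lower and a median of -0.07 (percentile 15.8), and the luminal list had 4 of 6 lower and a median of -0.12 (percentile 16.2), with miR-7 at -0.21 (spot SE 0.05).

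**Figure D2:**
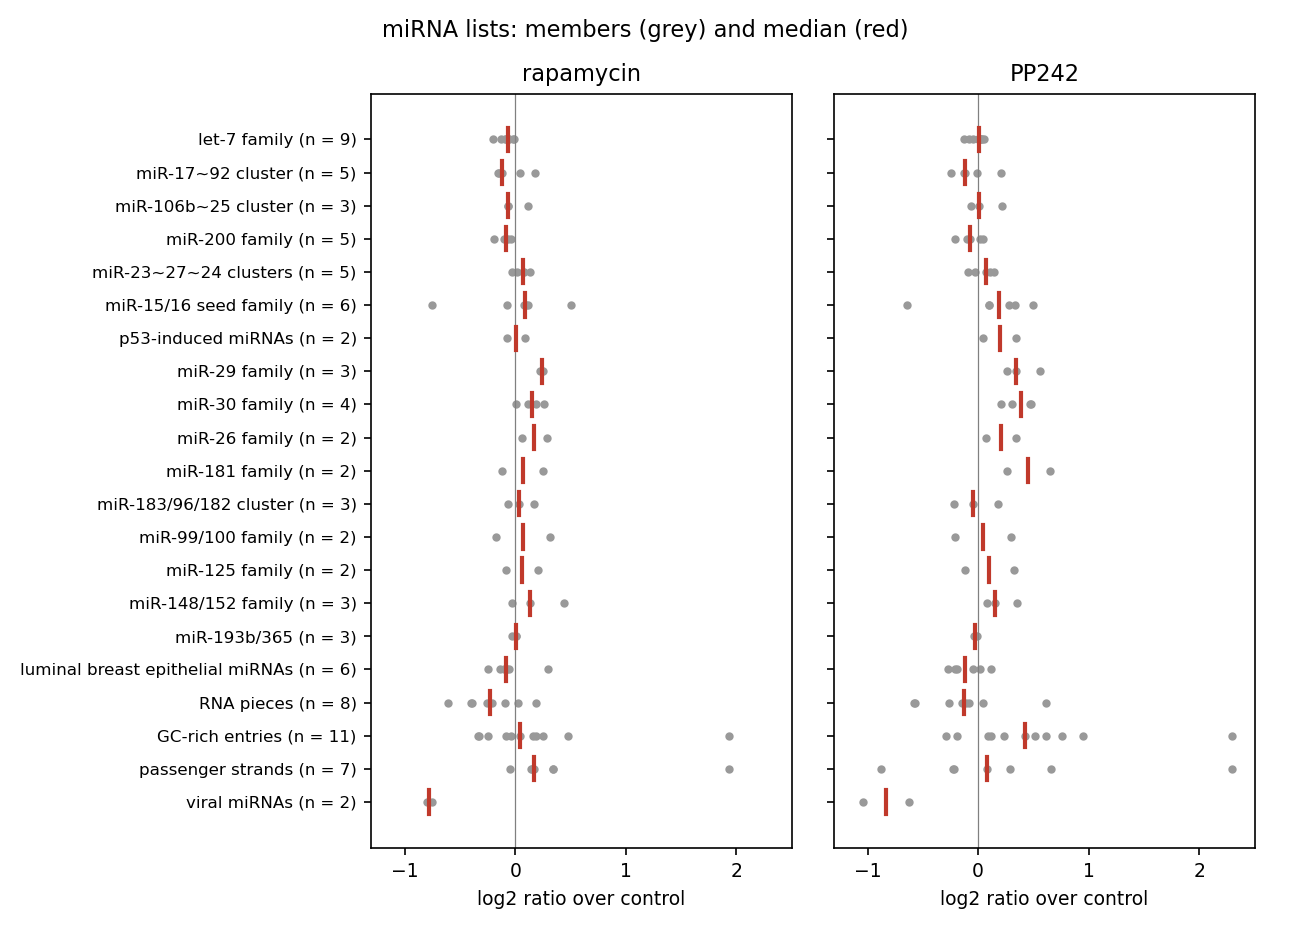
Log2 ratios over the control (x axis) of the members (grey points) and the median (red line) of the 21 miRNA lists with at least 2 members detected on all 3 arrays, with rapamycin (left) and PP242 (right), 1 array per group, so no error between samples is drawn. The miR-30 median lies at 0.15 and 0.39, the miR-29 median at 0.24 and 0.34, and the GC-rich entries' median at 0.05 and 0.43, higher with PP242; the let-7 median, at -0.07 and 0.01, sits close to 0.

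With PP242, too, 2 of the 21 lists lay outside the central 95% of random lists. A list of entries often bright on this array type, fixed under the name of GC-rich entries, had 9 of 11 members higher and a median of 0.43 (percentile 98.9). Among them were miR-1207-5p at 0.95 (spot SE 0.06), miR-1290 at 0.76 (spot SE 0.09), miR-1268 at 0.51 (spot SE 0.04) and miR-1202 at 0.12 (spot SE 0.05), besides miR-150*. miR-1290, miR-1305 and miR-574-5p are not GC-rich by their known sequences, which the files do not hold, and without them the median was 0.47 (percentile 99.0), a check made after the values were seen. The list came inside the range with quantile normalization, the median over spots, the deposited series values and, added after the values were seen, without miR-150* (0.33, percentile 97.1). With normexp its median turned to -0.72, at percentile 96.5, where the median over all miRNAs was -0.39, and with the refitted normexp it was 0.10 (percentile 99.1). The 2 viral entries had a median of -0.83 (percentile 1.29), which was lost under 5 of 17 alternatives. The list of structural RNA pieces had a median of -0.13 (percentile 5.02), with 6 of 8 lower, and with miR-923 added, again after its value was seen, it had -0.15 (percentile 1.82). Its member miR-1246, named after the values were seen, went the other way, at 0.615 (spot SE 0.095).

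Fewer detection calls separated PP242 from the control than separated rapamycin from it, with 30 miRNAs detected with PP242 and not in the control and 12 the other way. The bound reached 2-fold for 2 of the 30 and 9 of the 12. miR-1915 was 2.61-fold higher with PP242 and the neural strand miR-9* 2.51-fold, as ratios to control signals that were measured but not called detected. The bounds for lower levels, 8.29-fold for miR-609, 5.07-fold for miR-338-5p and 3.87-fold for miR-876-5p, rested on the same uneven control signals, which were not called detected with the spot medians. The call of ebv-miR-BART13 ended without scaling (-0.98) and with scaling to the 75th percentile over all entries (-0.80). The count of 1 higher and 1 lower became 3 and 0 with that scaling, 2 and 0 without scaling, 1 and 2 with median scaling, 1 and 3 with the labelling spike-ins, 0 and 25 with normexp, 0 and 0 with the refitted normexp and 3 and 19 with no detection filter.

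PP242 against rapamycin set inhibition of both complexes beside that of the rapamycin-sensitive part, at doses of 200 and 100 nM that differ. The arrays were close to each other: 157 of 161 miRNAs lay within 1.5-fold, 0 were at least 2-fold higher with PP242 and 2 were at least 2-fold lower. The 2 were miR-345 (-2.19, spot SE 0.59), with signals of 5.92 with PP242 and 31.5 with rapamycin, and miR-183* (-1.22, spot SE 0.34), with signals of 8.15 and 22.2. miR-150* differed by 0.35 (spot SE 0.31). Both members of the miR-181 family detected on all arrays were higher with PP242, miR-181a by 0.40 on the log2 scale (spot SE 0.07) and miR-181b by 0.38 (spot SE 0.04), and the list median of 0.39 lay at percentile 99.2. miR-21* was higher by 0.32 (spot SE 0.03), miR-29a by 0.32 (spot SE 0.06), miR-30c by 0.48 (spot SE 0.18) and miR-16 by 0.22 (spot SE 0.02), whereas miR-210 stood at -0.26 (spot SE 0.06) and miR-27a at -0.18 (spot SE 0.04). GC-rich entries had 10 of 11 members higher and a median of 0.35 (percentile 99.6), the widest member being miR-1207-5p at 0.90 (spot SE 0.04).

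Some groups did not separate the drugs by more than random lists did. The let-7 median was 0.08 (percentile 72.4), the miR-17~92 median 0.02 (percentile 21.6), the miR-29 median 0.12 (percentile 92.5) and the miR-30 median 0.16 (percentile 86.4), against 0.06 over all miRNAs. Between the drugs 36 miRNAs were detected with rapamycin alone and 2 with PP242 alone, and the bound reached 2-fold for 18 and 1 of these. The detection floor of the PP242 array was the signal of miR-345 itself, 5.92. In scaled signal it was 0.0115, against 0.0168 with rapamycin and 0.0199 in the control. Bounds computed from that floor, and the 2-fold call of miR-345, thus rest on 1 dim reading. Of the 34 detected with rapamycin on no other array, 22 were still called with the spot medians. By the ratio of both measured signals, miR-374b* was 8.1-fold lower with PP242 on the uneven signal given above, and miR-371-5p was 2.09-fold higher. The bound of 3.87-fold lower for miR-1226 came from a rapamycin signal of 26.8 with a spot SE of 16.7, which was not called detected with the spot medians. The 2-fold calls fell to 0 when miRNAs had to be well above background on all spots of a probe, and with the brightest probe only, and miR-183* turned to 0.14 with normexp and 0.18 in the deposited series values. The count of 0 higher and 2 lower became 18 and 1 with scaling to the 75th percentile over all entries and 1 and 24 with no detection filter, the miR-181 list came inside the range with the brightest probe (percentile 95.9), and the GC-rich list did so with quantile normalization and in the deposited series values.

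The log2 ratios of both drugs were correlated across miRNAs. miR-150* was the 1 miRNA at least 2-fold higher with each drug. Independent lists of these sizes would share 0.0075, a value that leaves the shared control out. Over the 133 miRNAs detected on all arrays, which are not independent replicates, Pearson's r between the log2 ratios was 0.820, Spearman's rho 0.753, and 73.7% had the same sign. Both ratios use the same control array, so unchanged arrays were simulated against 1 shared control. They shared 0.015 miRNAs at least 2-fold higher on average with spot error only and 0 with the spread between the drugs as noise. Neither simulation excludes a low reading of miR-150* alone on the control array. With spot error only the simulated r was 0.657 (95% range 0.389 to 0.856), the same-sign share 72.6% and the covariance 0.0078, against an observed covariance of 0.0881. With the spread between the rapamycin and PP242 arrays taken as noise, the simulated r was 0.499 (0.371 to 0.620), the same-sign share 66.8% and the covariance 0.022. Without miR-150*, an alternative chosen after the data were seen, r was 0.742 and the covariance 0.0557. With spot error only, the observed r lay inside the simulated range and the same-sign share was close to the simulated one, whereas the covariance was higher. The second simulation gave all 3 arrays equal noise, which sets r near 0.5, although the control array had the highest additive error. More noise on the control array would raise r and the covariance by itself, and a single control array cannot be split. The comparison therefore does not show a shared response to the drugs.

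**Figure D3:**
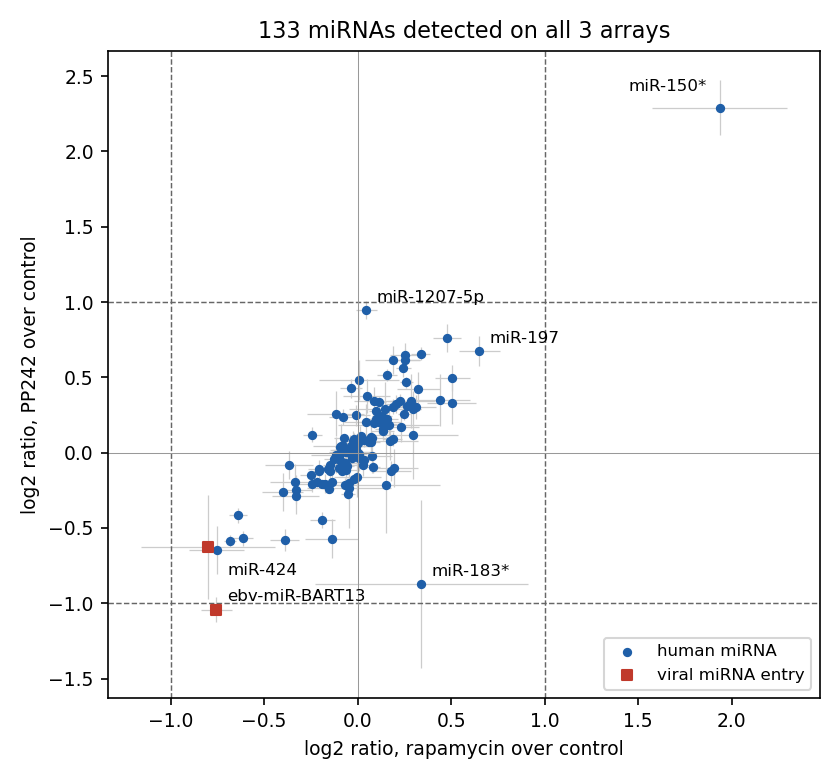
Log2 ratios of rapamycin over control (x axis) and PP242 over control (y axis) for the 133 miRNAs detected on all 3 arrays, human in blue and viral in red, with bars of 1 spot SE and dashed lines at 2-fold. miR-150* lies alone at 1.94 and 2.29, ebv-miR-BART13 at -0.76 and -1.04, and the remaining human miRNAs lie inside the dashed square.

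Counted over all 3 comparisons, 6 of 63 list medians lay outside the central 95% of random lists, where 3.2 would be placed by chance. They were the structural RNA pieces with rapamycin, the viral entries with each drug, the GC-rich entries in both PP242 comparisons and the miR-181 family between the drugs. miR-181 was thus the only miRNA family among them. The comparisons share arrays, so these medians are not independent.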

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

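The tests of faulty spots, of a shift of GC-rich entries and of dim miRNAs for miR-150* were chosen only after that result was seen; the other tests were written down first.

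Spike-in RNAs that Agilent's quality metric uses for the labelling step lie outside the comparisons and read higher on both treated arrays than on the control array. Spike-in dmr_285 was 1.37-fold above the control with rapamycin and 1.33-fold with PP242, and dmr_31a was 1.48-fold and 1.36-fold above it. The hybridisation spike-ins dmr_3 and dmr_6 had mean signals of 22604 and 20240 on the control array, 22731 and 19931 with rapamycin and 22530 and 20887 with PP242.

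The rapamycin array had 197 detected miRNAs against 145 on the control array. Brightness alone was argued against, since dividing its signals by the ratio of the 75th percentiles left 179 detected, more than the bound set in advance allowed. Raising each probe's error to that of the control array left 168, which decided neither way, and both changes together left 148, so the excess is consistent with higher noise on the control array combined with brighter signals on the rapamycin array. Isolated bright spots stay open as a part of it: of the 34 miRNAs detected on the rapamycin array alone, 22 were still called when each probe's mean was replaced by the median of its spots. A change of many dim miRNAs by rapamycin was not tested apart from these.

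miR-150* was higher on both treated arrays, although with normexp it read -1.01 with rapamycin and -0.72 with PP242, and 0.15 and 0.44 once the control array was refitted without 8 spots. With PP242, 2 probes were well above background on most of their spots, and the lower fold over the control was 3.59. The other of these probes read background on the control array, so the size of the rise rests on 1 probe. For PP242 the tables argue against faulty spots or a single probe as the source of the whole rise, since all 4 probes had their lowest scaled spot above the highest control spot. They also argue against a shift of all GC-rich entries. The 10 other detected ones of that list had a median log2 ratio of 0.005 with rapamycin (interquartile range -0.20 to 0.18). With PP242 it was 0.33 (0.10 to 0.59). Over the 7 left without miR-1290, miR-1305 and miR-574-5p the medians were -0.04 and 0.43. The 20 detected miRNAs nearest in control signal had a median of 0.054 (-0.23 to 0.22) over both drugs, against 2.11 for miR-150*. Dim miRNAs that stayed detected thus showed no such rise. That value cannot decide on a low reading of dim miRNAs on the control array, since those not called there were left out. Of the miRNAs not called on the control array, 28 were called on both treated arrays. For rapamycin they argue against faulty spots as the source of the whole rise, since 3 of 4 probes had their lowest scaled spot above the highest control spot, but whether it reached 2-fold cannot be told apart from faulty spots, because the lowest probe well above background was 1.88-fold above the control and another was uneven. A low reading on the single control array, of miR-150* alone or with other dim miRNAs, stays open for both drugs. So does a response of the cells to mTOR inhibition, which would need further control arrays. Whether these probes read miR-150* only was not tested, and the guide strand miR-150 was detected on no array.

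GC-rich entries were higher with PP242, with a list median of 0.43, although it was -0.72 (percentile 96.5) with normexp, 0.10 (percentile 99.1) with the refitted normexp and 0.33 (percentile 97.1) without miR-150*. A difference in hybridisation stringency cannot be told apart from it, since the probe ratio of dmr_3, the software's stringency spike-in, differed by 0.12 on the log2 scale (spot SE 0.16) and that of dmr_6 the other way, by -0.35 (spot SE 0.165). For a trend of the ratio with brightness, subtracting a running median over 31 miRNAs left a list median of 0.33, at percentile 97.8. This narrowly met the bound written in advance for arguing against such a trend. The resampling SE of 0.20, which was not part of that bound, does not separate the value from it, so the trend is left open. The list was fixed by name, and 3 of its members are not GC-rich by sequence. A response of these miRNAs to PP242 was not tested apart from both.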

How the results depend on the processing

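Scaling to the labelling spike-ins, leaving out miR-150*, the GC-rich list without 3 members, the structural RNA list with miR-923, the refitted normexp, an offset without normexp and the restriction to human miRNAs were chosen only after the data were seen. No paired analysis was possible because each group has 1 array, and for the same reason no array could be left out and no other split of the samples exists. The series values above 0 could not serve as an alternative detection call, since no value lies at or below 0. The order of miRNAs within a comparison does not depend on a scaling by 1 factor, but the zero point does: the median log2 ratio over detected miRNAs for rapamycin and PP242 against control was -0.01 and 0.04, and it was 0.28 and 0.10 without scaling, -0.23 and -0.33 with the spike-ins, -0.45 and 0.28 with the 75th percentile over all entries, -0.01 and -0.15 with median scaling, and -0.54 and -0.39 with normexp. Signal over background limits the dim miRNAs, and whether normexp moved them further than bright ones was not measured. On the control array 8 spots not above their local background drew its fitted background mean to -180.81, against 5.85 and 6.50 on the treated arrays, and to 4.76 without them. With this refit all 3 counts of 2-fold calls were 0 and miR-150* was at 0.15 and 0.44, and with only 50 added to each probe the counts were 0 as well and it was at 0.29 and 0.54. The sign turns against the control with normexp thus did not come from the offset. The offset alone was enough to bring the counts to 0 and miR-150* under 2-fold, so the refit cannot test those calls. For the other changes the cause was not tested.

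The count of miRNAs at least 2-fold apart for rapamycin against control was 1. It was 4 with the total gene signal, 34 with normexp, 8 with the 75th percentile over all entries, 4 with quantile normalization, 2 with the brightest probe, 5 with the mean of log2 over probes, 4 with odd-numbered spots, 5 with outlier spots kept, 19 with no detection filter, 5 with the deposited series values, 2 with the labelling spike-ins and 9 at 1.5-fold. For PP242 against control it was 2. It was 4 with the total gene signal, 25 with normexp, 5 with the mean of log2 over probes, 4 with odd-numbered spots, 6 with outlier spots kept, 22 with no detection filter, 4 with the series values, 4 with the spike-ins, 13 at 1.5-fold and 1 with human miRNAs only. For PP242 against rapamycin it was 2. It was 0 with normexp, 19 with the 75th percentile over all entries, 1 with quantile normalization, 0 with the brightest probe, 0 with the mean of log2 over probes, 4 with outlier spots kept, 25 with no detection filter, 0 with the stricter filter, 1 with the series values and 4 at 1.5-fold.

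The correlation of both treatments, 0.820, was 0.883 with the total gene signal, 0.990 with normexp, 0.90 with the mean of log2 over probes, 0.670 with no detection filter, 0.909 with the stricter filter and 0.742 without miR-150*. The number of lists apart from random lists, 2 in each comparison, was 1 for PP242 against control with quantile normalization, the mean of log2 over probes, the median over spots, even-numbered spots, the series values and without miR-150*. For PP242 against rapamycin it was 1 with quantile normalization, the brightest probe and the series values, and 4 with outlier spots kept. Other lists came outside the range. Over all 63 list medians these were 5 with outlier spots kept, 4 with normexp, and 2 each with the brightest probe, odd-numbered spots and the median over spots. There was 1 each with the total gene signal, the mean of log2 over probes, even-numbered spots and the series values. With normexp the sign turned for the pieces of structural RNAs with rapamycin (0.053), for the GC-rich list with PP242 (-0.718), for miR-150* with rapamycin (-1.01) and PP242 (-0.72), and for miR-183* between the drugs (0.14), which also turned in the series values (0.18), the refit (0.14) and with 50 added (0.10). The pieces turned without scaling, too (0.064), with the shift of all miRNAs. Under every alternative but normexp, miR-150* was above the control, from 0.15 to 3.47 with rapamycin and from 0.44 to 3.36 with PP242. The miR-15/16 family with PP242 came outside the range with the refit (percentile 98.3) and with 50 added (97.7). The detected counts of 145, 197 and 163 were 124, 169 and 145 when probes had to be well above background on at least 50% of their spots.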

Other observations

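Further fixed lists, with members counted where detected on all 3 arrays, stood within the central 95% of random lists in every comparison. The miR-26 family, known to repress EZH2, had both members higher, with medians of 0.17 (percentile 96) with rapamycin and 0.20 (percentile 82.9) with PP242, and miR-26a at 0.28 (spot SE 0.13) and 0.34 (spot SE 0.18). The family of miR-148a, miR-148b and miR-152 had medians of 0.14 (percentile 64.6) and 0.15 (percentile 64.0), with miR-148b at 0.14 and 0.15, a direction that turned relative to the median miRNA in the series values and, for PP242, also with quantile normalization. The clusters of miR-23, miR-27 and miR-24 had medians of 0.07 (percentile 89.2) and 0.07 (percentile 88.8). The miR-106b~25 cluster had -0.06 (percentile 28.8) and 0.01 (percentile 32.6), with its miR-25 at 0.12 and 0.21. The cluster of miR-183, miR-96 and miR-182 had 0.03 (percentile 66.0) and -0.05 (percentile 33.6), with miR-96 at -0.07 and -0.21. Between the drugs the median of this cluster was -0.08, at percentile 2.57, only just inside the range. The members of the miR-99/100 family went apart, miR-99a at 0.31 and 0.30 and miR-99b at -0.17 and -0.21, around medians of 0.07 (percentile 59.1) and 0.05 (percentile 30.6). So did those of the miR-125 family, miR-125b at 0.21 and 0.32 and miR-125a-5p at -0.09 and -0.12, around 0.06 (percentile 53.1) and 0.10 (percentile 49.0).

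The p53-induced list had 2 of 8 members detected on all 3 arrays, miR-34a at -0.08 and 0.04 and miR-192 at 0.09 and 0.34, with medians of 0.00 (percentile 40.2) and 0.19 (percentile 62.6). On each treated array 5 of the 8 were called detected, against 2 on the control array. The other 3 were less than 2-fold above control signals that were measured but not called detected. The ratios were 1.56-fold with rapamycin and 1.85-fold with PP242 for miR-215, 1.36-fold and 1.71-fold for miR-194, and 1.45-fold and 1.36-fold for miR-34b*. Neural miR-9 had such ratios of 1.78-fold and 1.77-fold. With each probe's error on the PP242 array raised to the control array's, 143 miRNAs were detected there, against 163 before and 145 on the control array. More calls on a treated array therefore do not by themselves show a rise. miR-193b and its neighbours in the list with miR-365 stayed within 0.04 of 0, with medians of 0.01 (percentile 59.7) and -0.03 (percentile 14.8). The 7 detected passenger strands had medians of 0.17 (percentile 80.9) and 0.08 (percentile 55.1), from -0.05 to 1.94 with rapamycin and from -0.87 to 2.29 with PP242, where the median was -0.07 without miR-150*. miR-20b, the 1 member of the miR-106a cluster detected on all 3 arrays, was at 0.07 and 0.09, and its miR-18b was detected with rapamycin alone, at least 2.13-fold above the control (signal 25.5, spot SE 5.32). Neural miR-128 was at 0.08 (spot SE 0.11) and -0.02 (spot SE 0.11). Relative to the median miRNA, the sign turned or the value became 0 under quantile normalization, the total gene signal or the series values for several of these groups: with both drugs for the miR-106b~25 cluster, the miR-23, miR-27 and miR-24 clusters and miR-20b, with rapamycin for the p53-induced list, the list with miR-365 and miR-128, and with PP242 for the miR-183 cluster, the miR-99/100 family and the passenger strands. Of the 4 miR-10 and miR-196 miRNAs of the HOX clusters, 0 were detected on the control array and 1 on each treated array.

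Among the 730 miRNAs detected on no array, single spots brighter than 50 were frequent on the control array (82 of 11680 spots) and the rapamycin array (88) and rare on the PP242 array (4). The software had marked 81, 88 and 4 of them as outliers. The value of 50 was chosen after the data were seen.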
